A study of Mus musculus with 2 samples.

How the data were processed

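Nuclei from mouse kidney were profiled by single-nucleus RNA sequencing in 2 libraries, 1 from a vehicle-treated and 1 from a cyclosporin A-treated sample. Per the labels, kidneys were snap-frozen, nuclei were isolated with a lysis kit and libraries were made with the 10x Genomics 3' kit v3.1. The submitters' processing notes name Cell Ranger 8.0.0 and the mouse genome build mm10. The deposited matrices hold UMI counts per gene and barcode, which were whole numbers of at least 1 with no normalization. The other deposited columns are barcode sequences and gene identifiers with symbols. Genes were matched by Ensembl ID to the GENCODE M21 annotation of mm10, which placed 32158 of 32285 genes (99.6%).

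Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1 and igraph 0.11.9, and R 4.3.3 with edgeR 4.0.16 and Seurat 5.3.0. Nuclei with at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 0 vehicle and 3 cyclosporin A nuclei. Doublets were called with Scrublet in each library at its automatic threshold, 554 (9.40%) and 697 (9.16%), and removed. Both libraries were clustered together without integration, on 2000 variable genes chosen within the libraries, 40 principal components and 15 neighbours, by Leiden clustering at resolution 1.0, which gave 30 clusters. A cluster took the name of the marker class, of 18, with the highest mean log2 level over the median cluster (pseudocount 10 CPM). At least 3 markers had to be 2-fold higher and the lead over the next class at least 0.3. Clusters with low UMIs and no own marker among their top 10 genes, or with more markers of another class there, stayed unnamed. Markers that also sit in gene lists are therefore not independent of the class names. Marker genes and gene lists were fixed before the data were examined, as were the comparisons and the rule for naming genes.

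UMIs were summed over the nuclei of each class and library and given as CPM, the sum scaled to the total UMIs of that class and library. CPM have exact Poisson 95% intervals, shares exact Clopper-Pearson 95% intervals, and the log2 ratio of cyclosporin A over vehicle the exact conditional binomial 95% interval of 2 Poisson counts. All cover counting error only, since nuclei of 1 library are not independent animals. Expression was compared in 10 classes with at least 50 nuclei in each library. Podocytes, lymphocytes, parietal epithelium and urothelium had fewer in at least 1 library, so the podocyte list gave no value. A count of 0 was set to a floor of 3 counts over the class. The fold at that floor is given, which can lie above the lower end of the exact interval. Retained nuclei held 28547425 UMIs in the vehicle and 42026962 in the cyclosporin A library.

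Genes were named by size in a class when they had at least 50 UMIs over both libraries, at least 50 CPM in 1 library and at least 20% of the level in the class with the highest level. They were ordered by the interval bound nearest 0, leaving out mitochondrial, ribosomal and unnamed genes. The rule took 12 genes each way in the proximal tubule, 5 each way in 7 other classes and 3 each way in thin limb, podocytes and myeloid nuclei. From each list it took 2 members each way, and it added Havcr1, Lcn2, Spp1, Vcam1, Slc12a1, Umod, Slc12a3, Trpm6, Calb1, Ren1, Egf, Rcan1, Ppp3ca and Kl where measured in their list. Krt20 and Sox9 came with the marker shares. Asns, Aqp3, Avpr2, Calr, Col4a1, Col4a2, Csf1, Fkbp5, Flt1, Hspa5, Kdr, Pck1, Pdia3, Pvalb, Slc34a1, Slc5a12, Sqle and Tsc22d3, members of the fixed lists, were picked as examples after their values were seen. Some single genes are not reported here.

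There were 30 fixed lists, each tied to 1 class or to all nuclei, and members needed 20 UMIs over both libraries. The median log2 ratio of a list has an order-statistic 95% interval over members and a percentile among 10000 random lists matched on expression in 20 bins, which describes these 2 libraries and is no test between groups. Injury marker shares were taken after thinning each nucleus at random to 1000 UMIs, leaving out shallower nuclei, with endothelium as background. The share of free RNA was estimated from 15 proximal tubule markers in endothelium, relative to their share of the library. Subtraction took that share from every class, without a separate estimate for each class.

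Alternatives were no nucleus filter, at most 2% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, libraries integrated by Seurat RPCA, TMM and median-of-ratios scaling, mean CPM per nucleus, free RNA subtracted, the proximal tubule without the injured cluster, list members with no minimum or 100 UMIs, and thinning to 500 or 2000 UMIs or none. Expression ratios and lists after RPCA or from nuclei with at least 1000 UMIs were added after the data were seen. So was free RNA subtraction for 3 lists in classes other than their own. So were injured shares without a nucleus filter, at 2% mitochondrial UMIs, after RPCA or from clustering without injury genes. On simulated counts with no difference, intervals held the true ratio for 95.6% to 96.0% of genes in 3 classes, and on counts with a set fold for 91.8% to 98.3% of smaller gene sets. Of 40 unchanged lists each in proximal tubule, distal convoluted tubule and myeloid nuclei, 0, 1 and 0 lay beyond percentiles 2.5 and 97.5, and lists with a set fold lay at percentile 100. Simulated genes were drawn independently and lists picked at random. The simulation therefore checks the calculation only, not how often a real list of related genes would reach such percentiles. Raw reads were not analysed here, so the empty droplets that would measure free RNA directly were not used.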

Results

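Single-nucleus RNA sequencing was done on mouse kidney after treatment with cyclosporin A, an immunosuppressant that blocks the phosphatase calcineurin, and on kidney of a vehicle-treated control. The labels describe the treated animals as a model of an early phase of the lasting kidney damage that such drugs cause. Each group was 1 library, so no replicate check was possible and no test between groups was run. The vehicle library held 5894 nuclei with 34934970 UMIs (unique molecular identifiers, each standing for 1 captured transcript) and the cyclosporin A library 7612 nuclei with 51449680 UMIs. After filtering and removal of called doublets, 5340 and 6912 nuclei were kept, with medians of 4589.5 and 4782.5 UMIs per nucleus. Below, log2 ratios are cyclosporin A over vehicle, brackets hold exact 95% intervals unless a list is named, and these intervals cover counting error only.

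The libraries also differed in measures of RNA quality. The nuclear RNA Malat1 took 12.3% of UMIs in the vehicle library and 7.99% in the cyclosporin A library, and mitochondrial transcripts took 0.0567% and 0.0317%. RNA free of nuclei, estimated from 15 proximal tubule markers in endothelium-like nuclei, made up 14.5% and 33.5% of the UMIs there.

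The question of the comparison was which cell types and genes of the kidney differ with cyclosporin A at this stage. Cell classes were named by markers, and each name stands for nuclei like that type, with the suffix left off after this point in most places. Proximal tubule-like nuclei, the cells that reclaim most filtered solutes, made up 42.6% of nuclei in the vehicle library (2275 nuclei, 41.3 to 43.9%) and 45.4% in the cyclosporin A library (3135 nuclei, 44.2 to 46.5%). Distal convoluted tubule-like nuclei, which fine-tune salt and magnesium, were 2.53% (2.12 to 2.99%) and 4.31% (3.84 to 4.82%), a 1.71-fold higher share (1.39 to 2.11). Myeloid-like nuclei were 1.87% (1.53 to 2.27%) and 3.04% (2.65 to 3.47%), 1.62-fold higher (1.27 to 2.08). Thin limb nuclei were 1.82-fold higher in share (1.48 to 2.24), principal cells 1.35-fold (1.11 to 1.64) and podocytes, from 25 and 65 nuclei, 2.01-fold (1.25 to 3.33). Endothelium-like nuclei were lower, at 15.7% (14.8 to 16.8%) and 13.6% (12.8 to 14.4%). Shares of thick ascending limb, connecting tubule, intercalated cell and stroma nuclei had ratios of 0.971, 0.929, 1.17 and 0.914. Small groups were lymphocytes, with 34 and 38 nuclei, and the parietal epithelium of the glomerular capsule, with 28 and 46.

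The direction of the proximal tubule share was not stable, with ratios of 1.06 (1.01 to 1.12) in the clustering used and 0.936 when the libraries were integrated by RPCA. A urothelium-like cluster held 179 and 27 nuclei (ratio 0.117), but at resolution 2 the ratio was 1.76. Nuclei without a marker name were 3.69% and 0.188%, most of them in a cluster with a median of 689 UMIs led by mitochondrial genes. Other settings left more cyclosporin A nuclei unnamed. At resolution 2 a like cluster held 153 and 14 nuclei and another 169 and 2, while a further unnamed cluster of shallow nuclei held 9 and 411. After RPCA, unnamed clusters held 148 and 1 and 238 and 478. In the clustering used, only 13 cyclosporin A nuclei were unnamed, so nearly all such shallow nuclei of that library stayed in named classes. Its proximal tubule nuclei numbered 3135 there, 2722 at resolution 2 and 2670 after RPCA. With vehicle they numbered 2275, 2271 and 2205. The proximal tubule class used may thus hold shallow cyclosporin A nuclei while like vehicle nuclei were left unnamed, which bears on its share and ratios.

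**Figure D1:**
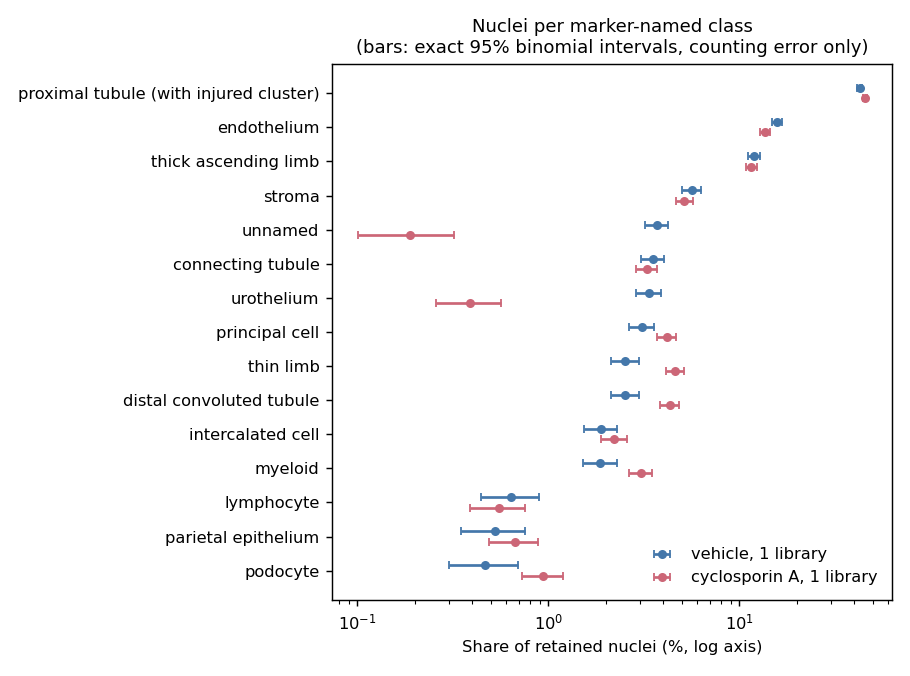
Share of retained nuclei (%, log axis) in each marker-named class for the vehicle library (blue) and the cyclosporin A library (red), 1 library each; points are shares and bars exact 95% binomial intervals. Distal convoluted tubule, thin limb and myeloid shares were higher with cyclosporin A (4.31%, 4.60% and 3.04%) than with vehicle (2.53%, 2.53% and 1.87%).

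Nuclei of the proximal tubule, thick ascending limb and endothelium split by library within their class. In the proximal tubule, clusters 3, 4 and 13 held 1011, 1025 and 195 vehicle nuclei but 3, 12 and 4 cyclosporin A nuclei, while cluster 27 held 13 and 1429. In the thick ascending limb, cluster 2 held 609 and 17 nuclei and cluster 24 held 22 and 458, and endothelial cluster 15 held 20 and 311. Distal convoluted tubule nuclei shared 1 cluster here, but at resolution 2 they split into clusters of 138 and 1 and of 6 and 298. Ratios below therefore compare whole classes, pooling these clusters.

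Injury genes were higher in the proximal tubule of the cyclosporin A library. Havcr1, which encodes kidney injury molecule 1, an apical receptor that damaged proximal tubule cells put on their surface, had 39 UMIs (2.23 CPM, the count scaled to the UMIs of its class and library; 1.58 to 3.04) with vehicle and 2444 (101 CPM; 96.8 to 104.9) with cyclosporin A, a 45.3-fold difference (33.0 to 63.8). Of 26 measured genes in the proximal tubule injury list, 23 were over 1.5-fold higher and 0 over 1.5-fold lower. The list median was a log2 ratio of 2.10 (order-statistic interval 1.02 to 3.34), at percentile 100 of 10000 matched random lists, and 1.24 without the injured cluster. Cd44, a hyaluronan receptor of injured epithelium, had 5 and 774 UMIs (log2 ratio 6.81 [5.58, 8.43]). Vcam1, an adhesion molecule of tubule cells that fail to recover, had 20 and 950 UMIs, 34.3-fold higher (22.1 to 56.5), and without the injured cluster its log2 ratio was 2.90. Outside that cluster, cyclosporin A proximal tubule nuclei held 42.9 CPM of Havcr1 and 5.99 CPM of Vcam1. In that library Havcr1 stood at 49.9 CPM in myeloid nuclei, 37.0 in stroma, 32.1 in endothelium and 16.3 in thick ascending limb. Vcam1 stood at 5.55 CPM in thick ascending limb. How much of the ratios outside the injured cluster is free RNA was not measured. Ccl2, a chemokine that draws monocytes, had 0 and 45 UMIs and was 10.8-fold higher with the 0 set to a floor of 3 counts. Lcn2, an early secreted marker of kidney injury, had 3 and 43 UMIs (3.37 [1.73, 5.71]), and Spp1, the secreted phosphoprotein osteopontin, 615 and 1729 (1.02). Havcr1 (ENSMUSG00000040405) lies on chromosome 11 at 46735080 to 46779578 of mm10, Vcam1 (ENSMUSG00000027962) on chromosome 3 at 116109949 to 116129688, and Cd44 (ENSMUSG00000005087) on chromosome 2 at 102811141 to 102901665.

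Nuclei carrying these transcripts were more frequent at equal depth. With every nucleus thinned to 1000 UMIs, 15 of 2233 vehicle proximal tubule nuclei (0.672%; 0.376 to 1.11%) and 316 of 2926 cyclosporin A nuclei (10.8%; 9.70 to 11.98%) had a UMI of Havcr1, Vcam1, Krt20, Lcn2 or Sox9. Endothelial nuclei, taken as the background, gave 15 of 802 (1.87%; 1.05 to 3.07%) and 57 of 911 (6.26%; 4.77 to 8.03%). In 12 of those 15 vehicle endothelial nuclei the gene was Vcam1, which endothelium makes itself, so this background is an upper bound. For Havcr1 alone the shares were 0.403% (0.185 to 0.764%) and 8.30% (7.33 to 9.36%), against 0 of 802 (up to 0.459%) and 2.63% (1.70 to 3.89%) in endothelium. Vcam1 shares of 0.134% and 2.46% lay at or below the endothelial 1.496% and 2.85%, where endothelium also makes the gene. Without thinning, its UMIs in the cyclosporin A proximal tubule sat in 253 nuclei, against 758.5 for an even spread by depth. Lcn2, at 0.0896% and 0.342% beside endothelial 0.249% and 0.768%, was not told from background. Krt20, a keratin of injured tubule cells, was found in 0 of 2233 nuclei, which allows up to 0.165%, and in 0.376% (0.188 to 0.672%) with cyclosporin A, beside endothelial 0 of 802 and 0.110% (up to 0.610%). Sox9, a factor of tubule repair, was found in 0.0448% and 0.308% (0.141 to 0.583%), beside 0.125% and 0 of 911 (up to 0.404%), so for both the intervals overlapped background. Before thinning, median depths were 7049 and 6998 UMIs in proximal tubule and 2278 and 2266 in endothelium, and the shares with any marker were 2.64% and 35.4% in proximal tubule and 3.21% and 13.8% in endothelium. Too shallow to thin were 42 and 209 proximal tubule and 39 and 29 endothelial nuclei.

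**Figure D2:**
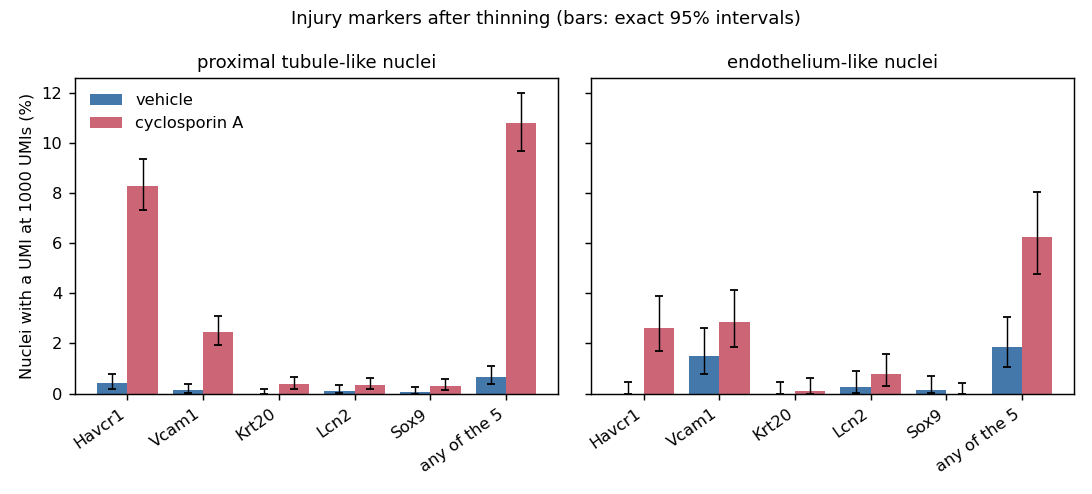
Percent of nuclei with at least 1 UMI of each injury marker, or of any of the 5, after thinning to 1000 UMIs, in proximal tubule-like nuclei (left) and in endothelium-like nuclei as background (right); blue is vehicle, red cyclosporin A, and lines are exact 95% intervals. Havcr1 stood at 0.403% and 8.30% in proximal tubule and at 0% and 2.63% in endothelium.

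A cluster of proximal tubule nuclei named by injury markers held 14 of 2275 vehicle nuclei (0.615%) and 733 of 3135 cyclosporin A nuclei (23.4%). The cyclosporin A share depended on the clustering, at 10.8% with doublets kept and 14.9% at resolution 2. Because the cluster was named by genes of the injury list, its size is not separate evidence on those genes.

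Ranked by the interval bound nearest 0, Kcnip4, which encodes a subunit that modulates potassium channels, came ahead of the other genes named by size in the proximal tubule. It had 418 UMIs (23.9 CPM) with vehicle and 29772 (1228 CPM) with cyclosporin A, 51.5-fold higher (46.7 to 56.8), with a log2 ratio of 3.48 once the injured cluster was left out. The cyclosporin A proximal tubule nuclei left then held 226 CPM of Kcnip4. That lay below endothelium (318), stroma (503) and myeloid nuclei (451) of that library, and above thick ascending limb (128). Free RNA may thus make up part of the 3.48, and its part was not measured. Sytl2, a vesicle docking factor, had a log2 ratio of 4.64 and Slc7a12, an amino acid transporter of the straight proximal tubule, one of 4.30 [3.91, 4.71]. Rad51b, a recombination repair gene, followed at 4.11, Plcl2, a phospholipase C relative, at 3.81 and Gadd45a, a DNA damage response gene, at 3.56. Nrg1, a growth factor of the epidermal growth factor family, had 2580 and 30873 UMIs and was 8.65-fold higher (8.31 to 9.004). Gpc3, a cell surface proteoglycan, and Unc13b, a vesicle priming factor, stood at 3.14 and 3.05, and Cftr, a chloride channel, and Plau, the urokinase protease, at 2.67 and 2.35. Leaving out the injured cluster lowered Havcr1, Sytl2, Nrg1 and Cftr to 4.30, 3.08, 2.27 and 1.06.

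Of the genes named by size in the proximal tubule, the lowest was Camk2b, a subunit of calmodulin-dependent kinase, with 901 and 19 UMIs, 65.6-fold lower (41.8 to 109.5). Ptpn22, a tyrosine phosphatase, had 2635 and 233 UMIs (-3.97), Slc16a14, of the monocarboxylate transporter family, 6354 and 894 (-3.30), and Rgs20, a regulator of G protein signalling, 11436 and 1849 (8.56-fold lower; 8.15 to 8.996). Polr3e, a subunit of RNA polymerase III, had 12929 and 3519 UMIs (-2.35). Dusp1, a phosphatase that shuts off stress kinases, and Gadd45g, of the Gadd45 stress family, stood at -2.75 and -2.42. Camk2b was also nearly missing from other cyclosporin A classes. The labels give no strain, and whether the genetic background of the animals differed was not tested, so its ratio cannot be assigned to treatment. The remaining low genes were Ano3 (-3.32), Angptl7 (-3.27), Kcnh4 (-3.00), Dnase1 (-2.74) and Arrdc2 (-2.41). Annotated genes on the same strand overlap some of these, Kcnip4 among them, so their own counts are less certain. Kcnip4 (ENSMUSG00000029088) lies on chromosome 5 at 48389502 to 49524907 and Camk2b (ENSMUSG00000057897) on chromosome 11 at 5969644 to 6066362.

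**Figure D3:**
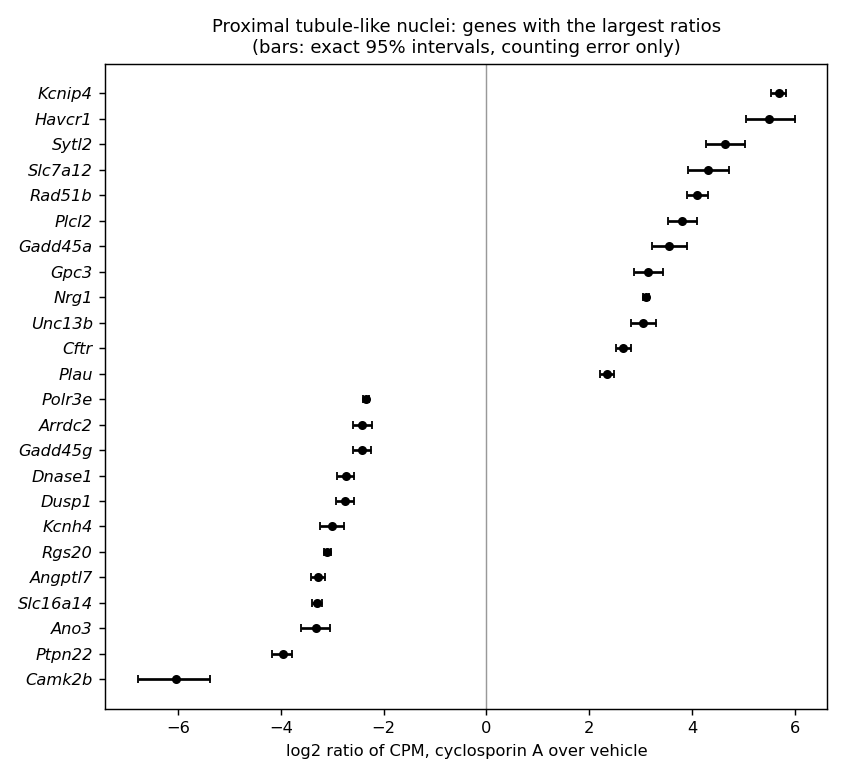
Log2 ratio of CPM, cyclosporin A over vehicle, for the 12 highest and 12 lowest named genes in proximal tubule-like nuclei; points are ratios and bars exact 95% intervals for counting error. Ratios ran from -6.04 for Camk2b to 5.69 for Kcnip4.

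Inflammatory genes were higher in the proximal tubule as well. In the NF-kB and chemokine list, 22 of 27 genes were over 1.5-fold higher and 0 over 1.5-fold lower (median 1.61, 1.21 to 2.70, percentile 100), and without the injured cluster the median was 0.72. Cxcl2, a chemokine for neutrophils, had 0 and 193 UMIs, 46.5-fold higher at the floor of 3 counts. Csf1, the macrophage growth factor, had 17 and 763 (5.02). Of the cyclosporin A UMIs of Cxcl2 and Csf1, 92.2% and 90.4% were in the injured cluster. Cfb, a complement component, stood at -0.37. With genes at a count of 0 set to the floor, the medians of the inflammatory and injury lists were 1.69 and 2.25. Of 32 interferon response genes, 16 were over 1.5-fold higher and 2 lower (0.57, -0.10 to 1.12, percentile 99.87). Without the injured cluster 7 of 29 were higher and 3 lower (0.34). Members included Ifit2 (2.89) and the antigen transporter Tap1 (2.78), while Xaf1 stood at -0.70. The p53 and cell cycle arrest list had 10 of 20 higher and 2 lower (0.56, 0.18 to 1.84, percentile 99.91), and 7 of 19 higher and 3 lower without the injured cluster (0.35). Its receptor Eda2r had 6 and 174 UMIs (4.39), with 85.6% of the cyclosporin A UMIs in the injured cluster. The cell cycle inhibitor Cdkn1a had 21 and 104 (1.84, and 0.61 without the injured cluster), and the kinase Plk3 stood at -1.88. Immediate early genes went both ways, 12 of 25 higher and 5 lower (0.52, -0.15 to 0.84, percentile 99.67), with the transcription factor Egr1 at 5.09 and the heat shock gene Hspa1a at -1.91. Their median was 0.08 (percentile 69.3) without the injured cluster and 0.25 (percentile 91.3) with members of at least 100 UMIs, so the shift was not stable.

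The endoplasmic reticulum stress list was lower in the proximal tubule, but its members moved apart. Of 30 genes, 17 were over 1.5-fold lower and 5 over 1.5-fold higher (median -0.75, -1.08 to -0.21, percentile 0.0). Among the lower members, Manf, a secreted stress protein, had 1502 and 476 UMIs (-2.13), Sdf2l1 stood at -2.38, Calr at -1.70, Pdia3 at -1.52 and the chaperone Hspa5 had 1495 and 876 (-1.24). Among the higher members, Trib3, a pseudokinase, had 2 and 270 UMIs (6.61 [4.74, 9.66]), the transcription factor Atf3 2 and 94 (5.09) and the asparagine synthetase Asns 11 and 326 (4.42). The glutathione-degrading Chac1 had 0 and 63, 15.2-fold higher at the floor of 3 counts, with a lower log2 bound of 3.58. Manf overlaps another gene on its strand, so its count is less certain.

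Metabolic lists differed in direction. Cholesterol and sterol synthesis genes were higher, 10 of 20 over 1.5-fold against 1 lower (0.58, 0.14 to 1.07, percentile 99.99), including the enzyme Sqle (1.35), while Idi1 stood at -0.81. Apical transport genes were more often lower than higher, 12 of 41 against 6 (-0.23, -0.49 to 0.07, percentile 0.0). The counts were 7 lower and 6 higher without the injured cluster (-0.08), and 9 and 6 with free RNA subtracted (-0.12). The glucose transporter Slc5a2 stood at -1.21, the phosphate transporters Slc34a1 and Slc34a3 at -0.94 and -1.54, and the lactate transporter Slc5a12 at -1.11, whereas the sulfate transporter Slc13a1 had 12841 and 55605 UMIs (1.65). Gluconeogenesis genes split, 3 of 13 higher and 4 lower (-0.21, -1.20 to 0.79, percentile 1.83). The glucose-releasing enzyme G6pc had 7632 and 3496 UMIs (-1.60) and Pck1, the rate-limiting enzyme, stood at -1.20, while the mitochondrial Pck2 had 32 and 206 UMIs (2.22). Fatty acid oxidation genes showed no common direction, 8 of 38 higher and 5 lower (0.08, -0.20 to 0.25, percentile 42.3), with Cyp4a14 at 1.96 and Acaa2 at -0.91.

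The oxidative stress, xenobiotic, sex-biased and hypoxia lists of the proximal tubule had medians of 0.17, 0.19, 0.03 and -0.10, at percentiles 81.8, 79.4, 20.6 and 12. Members over 1.5-fold higher and lower were 6 and 3 of 26, 8 and 7 of 28, 8 and 7 of 23, and 6 and 6 of 28. Without the injured cluster the xenobiotic and sex-biased medians were 0.31 and 0.40 (percentiles 98.5 and 99.6), and with free RNA subtracted the hypoxia median was -0.36 (percentile 0.49). Single members differed more. The efflux pump genes Abcb1a and Abcb1b, whose product transports many drugs, had log2 ratios of 2.10 and 3.13 [2.63, 3.67], and the glutathione transferase Gsta2 stood at 1.97. The sex-biased list holds genes of either sex, from Y-linked genes to Xist, so its median cannot show a shift toward 1 sex. Among its members the prolactin receptor Prlr stood at 2.80, while the androgen-dependent Kap had 23840 and 12476 UMIs (-1.40). Over all nuclei the Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y, looked at after the data were seen, also differed between the libraries (0.81, 0.68, 0.95 and 0.70). Uty stood at 391 and 685 CPM and Ddx3y at 131 and 210. Xist, the transcript of the inactive X chromosome, had 91 and 78 UMIs (3.19 and 1.86 CPM). Both libraries thus held Y-linked transcripts and little Xist, the pattern of male tissue. Whether the genetic background of the animals plays a part in these genes was not tested. The circadian clock list, which also holds glucocorticoid targets, was lower on balance, 8 of 25 against 3 higher (-0.21, -0.60 to 0.09, percentile 0.72), with the glucocorticoid-induced Fkbp5 at 19542 and 10252 UMIs (-1.40), Tsc22d3 at -1.14 and Sgk1 at -1.46.

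**Figure D4:**
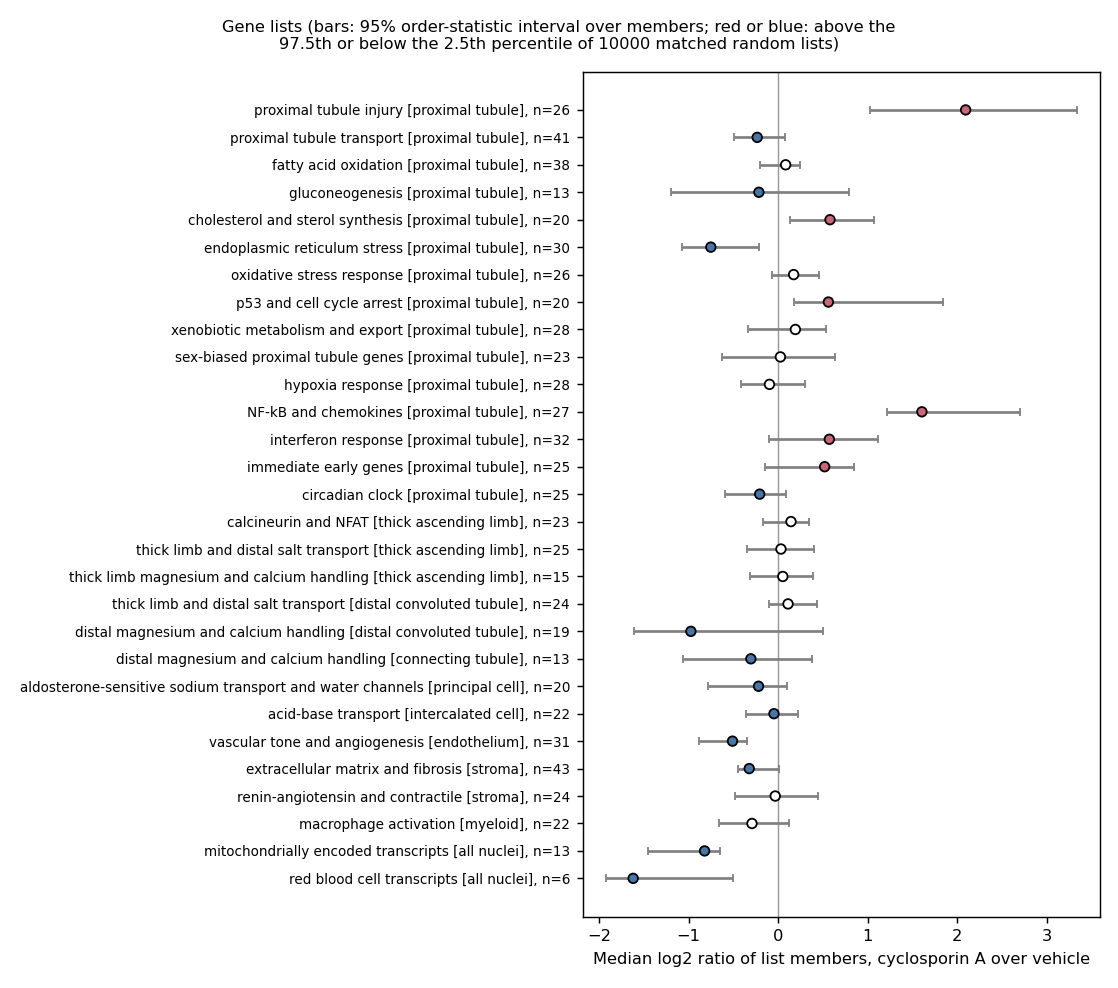
Median log2 ratio, cyclosporin A over vehicle, of the measured members (n) of each fixed gene list in the cell class in brackets; bars are 95% order-statistic intervals over members, and red or blue points lie above or below the central 95% of 10000 matched random lists. The proximal tubule injury list (2.10) and the NF-kB and chemokine list (1.61) were the highest and the red cell list (-1.62) the lowest.

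In the thick ascending limb, which reclaims salt and dilutes urine, the fixed lists stayed near 0. Calcineurin and NFAT genes had a median of 0.14 (percentile 81.2; 4 of 23 higher, 1 lower), salt transport genes 0.03 (percentile 10.1; 3 of 25 higher, 3 lower) and magnesium and calcium genes 0.05 (percentile 25.7; 2 of 15 higher, 2 lower). The calcineurin catalytic subunit Ppp3ca had 838 and 2421 UMIs (0.69), the NFAT factor Nfatc2 58 and 213 (1.04), and Rcan1, a calcineurin target and feedback regulator, stood at 0.23 [-0.17, 0.63]. Slc12a1, the salt cotransporter blocked by loop diuretics, had 34799 and 68257 UMIs (0.13), and Umod, the main urinary protein, 7432 and 7885 (-0.75). Genes named by size included Etnk2, a lipid kinase, with 9 and 303 UMIs (4.24), Nrxn3, a cell adhesion gene, with 411 and 3391 (2.21), Pla2g3, a secreted phospholipase, with 455 and 99 (-3.04), and Il7, a lymphocyte growth factor (-2.54). Kcnj15, a potassium channel gene, was 0.71 but -0.55 with doublets kept and -1.11 after RPCA.

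Magnesium and calcium handling genes were lower in the distal convoluted tubule. Of 19 measured genes, 12 were over 1.5-fold lower and 4 over 1.5-fold higher (median -0.97, -1.61 to 0.50, percentile 0.0). Calb1, a calcium-buffering protein, had 1952 UMIs (2630.2 CPM) with vehicle and 103 (51.8 CPM) with cyclosporin A, 50.8-fold lower (41.6 to 62.5). Slc8a1, the sodium-calcium exchanger, was 13.2-fold lower (12.5 to 14.0), from 7002 and 1423 UMIs. Trpm6, the apical magnesium channel, had 1829 and 1617 UMIs (-1.60 [-1.70, -1.50]), Pvalb, a calcium-binding protein of the early segment, 143 and 67 (-2.52 [-2.96, -2.09]), and Kl, the co-receptor for a phosphate hormone, stood at -1.61. The growth factor gene Egf, which acts on magnesium uptake, was 0.50 and its receptor Egfr 1.10. Salt transport genes had a median of 0.11 (percentile 19.5), with 4 of 24 higher and 1 lower. Slc12a3, the thiazide-sensitive salt cotransporter, had 8721 and 19183 UMIs (-0.28 [-0.32, -0.25]), and 0.02 once free RNA was subtracted. Dpp6, a potassium channel subunit, had 0 and 545 UMIs, 67.8-fold higher at the floor of 3 counts. Kcnj2, a potassium channel, had 4 and 171 (3.996). Slc12a3, Trpm6 and Pvalb were also markers that named this class, and Calb1 and Slc8a1 markers that named the connecting tubule. Over all nuclei Calb1 was 3.91-fold and Slc8a1 2.51-fold lower, so fewer late nuclei in this class may add to their ratios here. Calb1 (ENSMUSG00000028222) lies on chromosome 4 at 15881264 to 15908064, Slc8a1 (ENSMUSG00000054640) on chromosome 17 at 81373105 to 81738377 and Trpm6 (ENSMUSG00000024727) on chromosome 19 at 18749983 to 18892511.

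The connecting tubule had its own magnesium and calcium handling list, which shares only some genes with that of the distal convoluted tubule. In it 4 of 13 genes were over 1.5-fold lower and 2 higher (-0.30, -1.06 to 0.38, percentile 0.0). The median was -0.18 with doublets kept and -0.04 with free RNA subtracted. Calb1 had 2998 and 1466 UMIs (-1.62) and Slc8a1 45664 and 22347 (-1.62), while Trpm7, a magnesium-permeable channel kinase, stood at 1.07. Egf was 1.34, and 0.40 with free RNA subtracted, and Trpm6 was -0.35 but 0.32 with doublets kept. Kcnj2 had 6 and 155 UMIs (4.10) and Ier3, an early response gene, 146 and 13 (-4.08).

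In principal cells of the collecting duct, Slc14a2, the urea transporter of the inner medulla, had 480 and 47 UMIs, 25.9-fold lower (19.2 to 35.8), and Aqp2, the vasopressin-controlled water channel, 511 and 277, 4.68-fold lower (4.04 to 5.44). These nuclei formed 1 cluster (165 and 288), and whether its part from the inner medulla differed between the libraries was not tested. In the list of aldosterone-sensitive sodium transport and water channels, 6 of 20 genes were lower and 1 higher (-0.22, -0.79 to 0.10, percentile 0.01), and the median was -0.41 with doublets kept. Its members Aqp3, a basolateral water channel, and Avpr2, the vasopressin receptor, stood at -1.78 and -1.32, and Scnn1b, a sodium channel subunit, at 0.52. Aqp2, Aqp3, Avpr2 and Scnn1b were also markers that named the class, and Slc14a2 a marker of the thin limb. Ly6e, a surface protein induced by interferon, was among the genes named as higher, with 5 and 308 UMIs (4.60). Slc14a2 (ENSMUSG00000024552) lies on chromosome 18 at 78146148 to 78596942 and Aqp2 (ENSMUSG00000023013) on chromosome 15 at 99579055 to 99584547.

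Acid-base genes of intercalated cells were near 0, with 1 of 22 higher and 1 lower (-0.05, percentile 0.52), and with free RNA subtracted 4 of 21 were higher and 0 lower (0.17, percentile 16.2). The bicarbonate exchanger Slc4a1 was -0.85 and Car15, a carbonic anhydrase, 1.30. Camk2b and Lrrc31, a leucine-rich repeat gene, were nearly missing from several cyclosporin A classes, with the same open question of genetic background. Lrrc31 had 1081 and 1 UMIs in the thick ascending limb (-10.92 [-16.22, -8.44]), 205 and 4 in intercalated cells (-6.34), 125 and 17 in principal cells (-4.22) and 66 and 4 in thin limb (-5.78). Camk2b had 117 and 4 UMIs in principal cells (-6.21), 89 and 1 in intercalated cells (-7.14 [-12.46, -4.62]) and 88 and 1 in thin limb (-8.20 [-13.52, -5.68]). Lrrc31 (ENSMUSG00000074653) lies on chromosome 3 at 30679058 to 30699843.

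Vascular genes were lower in endothelium, 14 of 31 over 1.5-fold against 2 higher (-0.51, -0.88 to -0.35, percentile 0.0), and with free RNA, 14.5% and 33.5% of UMIs, subtracted 7 of 30 were lower and 2 higher (-0.35). With doublets kept, 18 of 31 were lower. The vascular growth factor receptors Kdr and Flt1 stood at -0.85 and -0.77, the prostacyclin synthase Ptgis at -2.54 and the peptide hormone Apln at -2.22, while Vcam1 was 1.08 and Edn1, which encodes the vasoconstrictor endothelin, had 12 and 34 UMIs (1.28). Kcnmb2, a potassium channel subunit, had 1 and 377 UMIs (8.34 [5.85, 13.64]). Kcnip4 was also among the genes named as higher in endothelium (4.35, and 2.43 with free RNA subtracted), stroma (5.30, and 5.02), myeloid nuclei (4.67, and 4.05) and thin limb (3.98). In thin limb no UMIs of the cyclosporin A library were left after the subtraction, which takes the endothelial share from every class. Kcnip4 stood at 796 CPM over all cyclosporin A nuclei, 200 in thin limb, 128 in thick ascending limb and 114 in intercalated cells. For this gene the subtraction took off more than these classes held. Values with free RNA subtracted may therefore be over-corrected in tubule classes. How much of Kcnip4 in other classes is free RNA was not measured.

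Matrix genes of the stroma, which lay down scar tissue, were not higher as a group. Of 43 genes, 12 were over 1.5-fold lower and 8 higher (-0.32, -0.45 to 0.01, percentile 0.01), and the median was 0.02 with free RNA subtracted and -0.21 with no minimum of UMIs. Ccn2, a matrix growth factor, had 850 and 214 UMIs, 4.01-fold lower (3.45 to 4.68), and Col4a1 and Col4a2, chains of basement membrane collagen, stood at -1.16 and -1.24. Serpine2, a protease inhibitor, was 1.16 and Fap, a protease of activated fibroblasts, had 6 and 27 UMIs (2.16). Igfbp3, a growth factor carrier, had 747 and 146 UMIs, 5.17-fold lower (4.32 to 6.21). Renin and contractile genes had a median of -0.03 (percentile 30.1; 6 of 24 higher, 6 lower), -0.32 with doublets kept and 0.07 with free RNA subtracted. Among them Ren1, the renin gene, had 36 and 71 UMIs (0.97 [0.37, 1.59]), with a log2 ratio of 0.25 when nuclei were weighted alike. Ccn2 (ENSMUSG00000019997) lies on chromosome 10 at 24595442 to 24598683 and Ren1 (ENSMUSG00000070645) on chromosome 1 at 133350510 to 133360325.

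In myeloid nuclei, the macrophage activation list had a median of -0.29 (percentile 5.48), with 2 of 22 genes higher and 6 lower, and of 0.03 with free RNA subtracted. The cytokine Il1b and the complement gene C1qa stood at -1.62 and -1.42, and the integrin Itgam at 0.64. Txndc5, a disulfide isomerase of the reticulum, had 60 and 5 UMIs (-4.79). TMM scaling moved all genes of this class by 0.12 on the log2 scale and median-of-ratios scaling by 0.16.

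Over all nuclei, mitochondrial transcripts were lower, 13 of 13 by over 1.5-fold (-0.82, -1.45 to -0.64, percentile 0.02), and so were red cell genes, 5 of 6 with 0 higher (-1.62, -1.92 to -0.50, percentile 0.14), such as the globin gene Hbb-bs (-1.86). Malat1 was lower in tubule classes, such as proximal tubule (-0.78), principal cells (-0.78), intercalated cells (-0.73) and thick ascending limb (-0.54), but close to 0 in endothelium (-0.01) and higher in myeloid nuclei (0.28).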

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

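Expression ratios and lists after RPCA or from nuclei with at least 1000 UMIs, lists in other classes with free RNA subtracted, and injured shares without a nucleus filter, at 2% mitochondrial UMIs, after RPCA or without injury genes, were chosen only after the results were seen. No paired analysis was possible because each group was 1 library, and no value could be checked without 1 library. Of single expression ratios under the alternatives run, 1417 stayed within the main interval, 211 moved and 4 reversed. The reversed ones were Kcnj15 in thick ascending limb (-0.55 with doublets kept, -1.11 after RPCA), Slc12a3 in distal convoluted tubule (0.0225 with free RNA subtracted) and Trpm6 in connecting tubule (0.32 with doublets kept). Settings differed widely: TMM scaling moved 4 ratios and left 221. Without the injured cluster 43 proximal tubule ratios moved and 36 stayed. With free RNA subtracted 57 moved, 1 reversed and 145 stayed. Ratios that lost all UMIs of a library in that subtraction gave no value and are not counted. Of list medians 213 stayed within the interval over members, which is often wide, and 3 moved: NF-kB and chemokines to 0.72 without the injured cluster, and with free RNA subtracted the vascular list to -0.35 and the matrix list to 0.0187. Of 3 lists in other classes 21 medians stayed and 5 moved with free RNA subtracted. The ratio of proximal tubule shares was 0.926 at resolution 2, 0.932 without a nucleus filter, 0.936 after RPCA and 1.00 at 2% mitochondrial UMIs. That of the urothelium-like cluster was 1.76 at resolution 2 and 0.805 after RPCA, and that of connecting tubule 1.18 with doublets kept. The injured share of cyclosporin A proximal tubule was 14.9% at resolution 2, 10.8% with doublets kept, 26.8% without a nucleus filter and 28.5% after RPCA; resolution 0.5 and clustering without the injury genes named no injured cluster. The share with any marker was 0.132% (vehicle) and 6.57% (cyclosporin A) at 500 UMIs, 16.1% (cyclosporin A) at 2000, and 2.64% and 35.4% unthinned, as fewer UMIs leave fewer nuclei with 1. Otherwise the cause was not tested. Free RNA subtraction gave no value for the mitochondrial and red cell lists. Elsewhere it took the share estimated in endothelium from every class, which may be too much in tubule classes. Depth limits genes with few UMIs: Lcn2, with 3 and 43, had an interval of 1.73 to 5.71.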

Other observations

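All but 2 of the tests below were chosen only after the results were seen; the exceptions are the dilution test and the test of nuclei with at least 3 Havcr1 UMIs. The lists in classes other than their own, and the genes of the next 2 paragraphs, were also chosen after their values were seen.

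Interferon response genes were lower in vascular and immune classes, in contrast to the proximal tubule. In endothelium 21 of 35 measured genes were over 1.5-fold lower and 0 higher (median log2 ratio -0.76), in myeloid nuclei 18 of 25 lower and 1 higher (-0.78), and in stroma 11 of 28 lower and 0 higher (-0.43), each at percentile 0.0 of 10000 matched lists. Free RNA was higher in the cyclosporin A library, and with it subtracted these medians were nearer 0, at -0.45 in endothelium (13 of 35 lower, percentile 0.0), -0.49 in myeloid nuclei (9 of 24 lower, 0.04) and -0.28 in stroma (5 of 28 lower and 2 higher, 1.12). In principal cells 10 of 18 were higher and 3 lower (0.71, percentile 99.99). Isg15, an interferon-induced ubiquitin relative, had 37 and 12 UMIs in endothelium (-1.85), and Rnf213, a large ubiquitin ligase of vessels, 979 and 637 (-0.84) there but 910 and 2204 in proximal tubule (0.81). The endoplasmic reticulum stress list was lower in thick ascending limb (-0.49), thin limb (-0.50), principal cells (-0.52), intercalated cells (-0.56) and myeloid nuclei (-0.70), with smaller medians in stroma (-0.21), endothelium (-0.15), distal convoluted tubule (-0.07) and connecting tubule (-0.05). With free RNA subtracted the endothelial median was 0.04 and that of the distal convoluted tubule -0.15. Cholesterol genes had medians of 0.86 in stroma (percentile 99.97), 0.75 in thin limb (98.97) and 0.41 in endothelium (98.88). In the other 6 classes, from -0.42 in thick ascending limb (4.75) to 0.43 in connecting tubule (95.4), they lay within the central 95% of matched lists. The cholesterol medians were not stable to free RNA, since with it subtracted stroma stood at 0.46 (97.2), thin limb at 0.28 (79.8), endothelium at 0.30 (97.6), connecting tubule at 0.67 (99.3), principal cells at -0.42 (13.8) and thick ascending limb at -1.39 (0.02). The subtracted share was estimated in endothelium and may be too high for tubule classes. Whether these classes differ from each other was not tested.

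Some proximal tubule genes sat in few nuclei. Cd44 was found in 179 cyclosporin A nuclei, against 642.1 if its UMIs were spread evenly by depth, with 91.2% of them in the injured cluster. Vcam1 was found in 253 against 758.5. Slc7a12 was found in 259 against 1072.7, but only 4.12% of its UMIs were in the injured cluster. Spp1, in 1243 against 1181.4, and Hspa5, in 663 against 710.7, were close to an even spread. Several genes were nearly all in 1 library over all nuclei, with 1409 and 43 UMIs for Camk2b, 1656 and 34 for Lrrc31, 39 and 841 for the zinc finger gene Zfp984, and 7 and 269 for Zfp979. Whether the genetic background of the animals differed was not tested.

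Injury marker UMIs were more frequent in proximal tubule nuclei of the cyclosporin A library. A difference in depth was argued against, since at 1000 UMIs in every nucleus the shares were 0.672% and 10.8%, with intervals apart. Free RNA as the whole source of Havcr1 UMIs was also argued against, since 8.30% of proximal tubule nuclei had one at that depth and 2.63% of endothelial nuclei did. For free RNA spread evenly over nuclei, the test fixed in advance came out on its side, with 7.43% of nuclei holding at least 3 Havcr1 UMIs beside 7.34% for a Poisson draw, but the 932 nuclei with a UMI, against 1471.8 for an even spread, and the endothelial share speak against it. An effect of cyclosporin A on the tubule stays open and untested, as does any other difference between the 2 samples, since treatment and library cannot be separated with 1 library per group.

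Magnesium and calcium handling genes were lower in distal convoluted tubule-like nuclei. Fewer late distal nuclei in the class was argued against as the whole cause for Trpm6 and Pvalb, which the early part also makes. Trpm6 (-1.60, upper bound -1.50) and Pvalb (-2.52, upper bound -2.09) were lower too. For Calb1 and Slc8a1, markers of the connecting tubule, it stays open. Calb1 stood at 2630 CPM here and 3099 in connecting tubule with vehicle, and at 51.8 and 1006 with cyclosporin A. Slc12a3 in connecting tubule was lower as well (-1.31), and over all nuclei Calb1 was 3.91-fold lower. For free RNA, the list median was -0.97 without and -1.22 with its subtraction. The subtraction took the share estimated in endothelium, which may be too much in tubule classes and can itself lower the median. It therefore cannot decide, and free RNA stays open. A fall in these transcripts with cyclosporin A may account for the pattern, but it was not tested, and a difference between the 2 samples unrelated to treatment stays open as well.

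Transcripts of unnamed gene models and antisense genes were lower in the cyclosporin A library, with 1700 of 2526 lower in proximal tubule. Their share of UMIs was 4.82% and 3.69% there, but nearly alike in stroma (4.46% and 4.43%), endothelium (4.56% and 4.32%) and myeloid nuclei (5.11% and 4.91%). Dilution of nuclear RNA by free RNA was argued against as the whole cause, since their proximal tubule median was -0.59 (-0.68 to -0.49) and the free RNA shares allow -0.36. A difference between the libraries that all nuclei share is a candidate explanation for the medians, since in 10 of 10 classes that of these models lay over 0.3 below that of named protein-coding genes, but it leaves the unequal UMI shares open. Such a difference may lie in nuclear isolation, in sequencing or in the animals, and a treatment effect on all cell types is not excluded.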
